A study of Homo sapiens with 21 samples.

How the data were processed

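RNA from BT474 cells and 4 resistant pools was sequenced in 21 libraries, 3 per group in 7 groups. The deposited count table holds raw read counts per gene, per the labels made with Bowtie2 and featureCounts on build hg38. The authors also deposited values on a log2-like scale, the variance-stabilizing transformation of normalized counts from DESeq2; the versions and settings of these tools were not stated, nor was strandedness. The counts were used for every comparison, and the deposited transformed values for an alternative.

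Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group (minimum count 10, minimum total count 15), which left 17650 of 37355 genes. Libraries were normalized by TMM. All 21 libraries entered 1 fit with a term per group and no other covariate, with 14 residual degrees of freedom, and each comparison used edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over the tested genes. A gene was called at an adjusted p under 0.05. Calls shared by pools needed that in each pool with the same direction. Values are log2 fold changes with standard errors, and CPM, counts scaled to the normalized library size, with standard deviations. Gene positions came from GENCODE 29 on hg38, which gave a position for 36530 genes.

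The samples, groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where an alternative or a test is said to have been chosen after seeing the data. Of the genes with an adjusted p under 0.05, a symbol, a mean of at least 5 CPM over the samples compared and no overlap between replicates, the 6 with the largest rise and the 6 with the largest fall were named in each comparison. For shared calls the ranking used the smallest change over the comparisons. Members of called lists were named by size of change, of which the first few are given. Of 11 genes to be reported in every group, 10 are given, and not every member that the rule names is reported. The 38 lists of pathway, amplicon and cell type genes were tested with camera in limma 3.58.1 on z-scores from the edgeR fit, at a preset correlation of 0.01 between genes, over the 37 lists with at least 3 tested members. List counts adjusted over the list alone, an estimated correlation and fry stand beside it. With the preset correlation 91 list tests were called over the 7 comparisons, and 17 with an estimated correlation.

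Alternatives were no filter, a strict filter (CPM of 1 in 3 samples and a total of 10), RLE normalization, library size alone, DESeq2 1.42.0, limma on the deposited transformed values, only the groups compared, replicate number as a block, a fold threshold of 2, and leaving out each library in turn. Chosen after seeing the data were replicates 2 and 3 alone, a correction of each library for GC content (spline with 5 degrees of freedom, 17554 genes with a GC value), this correction with the block, thinning to the shallowest library and, for the share of falls and gene windows alone, the GC correction with the median of its shifts or of all changes set to 0. A range beside an alternative's adjusted p runs over all alternatives of that result. A library left out leaves a group with 2 libraries, and edgeR's pooled spread was used.

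Library totals ran from 7939270 to 21746391 counts. Between replicates, counts varied 5.40 to 79.7 times more than counting error alone (chi-square per degree of freedom), so precision was set by replicate spread. In simulated data, 14.93% of genes changed 1.5-fold, 61.19% of genes changed 2-fold and 92.42% of genes changed 4-fold were recovered, with 10 of 122 calls among unchanged genes. Without a change, the calls numbered 0. Intervals and floors cover counting error only.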

Results

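RNA was sequenced from BT474, a human breast cancer cell line with amplified ERBB2 (HER2), and from antibody-resistant pools derived from it. The 21 libraries formed 7 groups of 3. The groups were untreated cells, cells given 10 µg/mL trastuzumab for 3 days, and cells given 10 µg/mL each of trastuzumab and pertuzumab for 3 days. The others were the trastuzumab-resistant pools BT-TR1 and BT-TR2 and the pools BT-TPR1 and BT-TPR2, resistant to both antibodies, which were kept without antibody for 7 days before harvest. Total counts for replicates 1, 2 and 3 were 20287901, 19516112 and 21746391 in untreated cells, 20878152, 20280460 and 20546421 with trastuzumab, and 20323746, 19324898 and 20471764 with both antibodies. They were 13432287, 11970803 and 7939270 in BT-TR1, 17472244, 17886199 and 15186744 in BT-TR2, 16737677, 14122216 and 14960321 in BT-TPR1 and 17483736, 19559313 and 15880398 in BT-TPR2. Of 37355 genes in the count table, 17650 passed the filter and were tested.

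By correlation of log2 CPM, replicate 1 stood apart in each group but BT-TR1. Across genes, the deviation of a replicate 1 library from its group mean correlated with the gene's GC content (r from 0.293 to 0.584), against -0.499 to 0.0671 in the other libraries. These correlations are across genes, which are not independent replicates. Mitochondrially encoded transcripts took 33.3% of counts in trastuzumab replicate 1, 29.8% in replicate 1 with both antibodies and 24.5% in untreated replicate 1, and between 13.7% and 21.9% in the other libraries. Across genes, the change in BT-TR1 against untreated cells correlated with GC content at r = -0.448, against -0.0847 in BT-TR2. The replicate numbers paired libraries in 8 of the 11 comparisons, so each count of genes also has a value with replicate number as a block. They did not pair for both antibodies against untreated cells or for BT-TPR1 or BT-TPR2 against BT-TR1. The labels do not say how independent the replicates of a group were, so each p measured only the spread between these libraries. Each resistance class had 2 pools, and the pools, not the libraries, are the units of resistance.

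**Figure D1:**
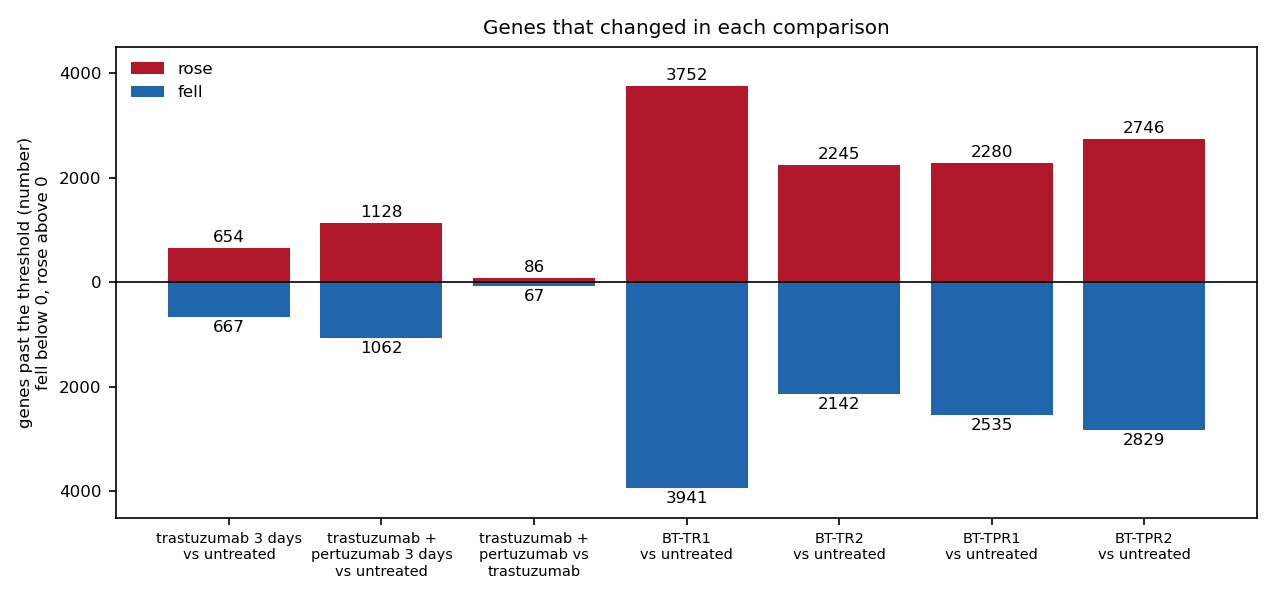
Number of genes (y axis) that rose or fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test in each comparison (x axis), 3 libraries per group. The bars run from 153 genes for both antibodies against trastuzumab alone to 7693 genes for BT-TR1 against untreated cells.

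ERBB2, whose product HER2 is the target of both antibodies, was abundant in every group. Levels are read counts scaled to the normalized library size (CPM, mean ± SD, n = 3), in the order untreated, trastuzumab, both antibodies, BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2. ERBB2 (ENSG00000141736.13, chromosome 17, 39687914 to 39730426, hg38) stood at 8184 ± 1922, 6007 ± 636, 5491 ± 1116, 5444 ± 1183, 7700.1 ± 1641, 5919.7 ± 1300 and 6829 ± 2139 CPM. Its log2 fold changes against untreated cells lay between -0.59 and -0.09 and passed the test in no comparison, the nearest being BT-TR1 (-0.59 ± 0.24, adjusted p = 0.053), which does not show that its levels were equal. ERBB2 passed with the replicate block with trastuzumab (-0.42, adjusted p = 0.0226, range 0.0226 to 0.654), with both antibodies (-0.57, adjusted p = 0.00212, range 0.0012 to 0.409), in BT-TR1 (-0.58, adjusted p = 0.000709, range 0.000126 to 0.317) and in BT-TPR1 (-0.46, adjusted p = 0.00685, range 0.00685 to 0.53). It passed under 10 of 33 alternatives in BT-TR1 and 4 of 33 with both antibodies. With the GC correction, chosen after seeing the data, the BT-TR1 value turned to 0.16, with a median shift over all genes of -0.162. EGFR stood at 45.2 ± 2.42, 50.3 ± 4.93, 61.8 ± 6.61, 72.3 ± 5.46, 70.9 ± 8.64, 78.7 ± 14.9 and 101 ± 4.22 CPM. With trastuzumab its change (0.15 ± 0.13, adjusted p = 0.523) did not pass. It rose with both antibodies (0.45 ± 0.13) and in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (0.68 ± 0.13, 0.65 ± 0.13, 0.80 ± 0.13 and 1.16 ± 0.13). ERBB3, the kinase-impaired partner of HER2, stood at 533 ± 15.9, 611 ± 41.2, 637 ± 62.3, 549.8 ± 34.6, 486 ± 28.4, 487 ± 60.5 and 554 ± 90.7 CPM and passed no test against untreated cells, with changes between -0.13 and 0.26. ERBB4 stood at 15.1 ± 2.10, 12.3 ± 0.722, 7.08 ± 1.26, 5.84 ± 1.17, 8.54 ± 0.643, 17.2 ± 1.27 and 14.5 ± 1.68 CPM, and fell with both antibodies (-1.09 ± 0.15), in BT-TR1 (-1.36 ± 0.16) and in BT-TR2 (-0.82 ± 0.15). The ERBB4 changes that did not pass lay between -0.30 and 0.20, though with trastuzumab it passed with the GC correction and replicate block, at -0.36 (adjusted p = 0.0227, range 0.0227 to 0.6). The EGFR call with both antibodies ended without untreated replicate 2 or 3 (adjusted p = 0.0866 and 0.0551), without trastuzumab plus pertuzumab replicate 1 or 3 (0.0861 and 0.0626), with only the groups compared (0.075) or with thinning (0.117), range 0.00178 to 0.117.

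In the same order of groups, the estrogen receptor gene ESR1 stood at 81.5 ± 6.43, 72.8 ± 6.28, 56.9 ± 4.88, 41.6 ± 3.64, 44.3 ± 1.28, 57.4 ± 1.52 and 45.7 ± 4.23 CPM, and fell with both antibodies (-0.52 ± 0.10) and in the 4 pools (-0.97 ± 0.10, -0.88 ± 0.10, -0.50 ± 0.10 and -0.83 ± 0.10). With trastuzumab its change (-0.16 ± 0.10, adjusted p = 0.36) did not pass. PGR, the progesterone receptor gene, stood at 522 ± 63.1, 774 ± 173, 455 ± 87.8, 193 ± 24.7, 204 ± 18.6, 707 ± 67.1 and 178 ± 21.2 CPM. It rose with trastuzumab (0.57 ± 0.17) and fell in BT-TR1 (-1.44 ± 0.17), BT-TR2 (-1.35 ± 0.17) and BT-TPR2 (-1.55 ± 0.17). Its other changes, -0.20 and 0.44, did not pass. With the GC correction and replicate block ESR1 passed with trastuzumab, at -0.24 (adjusted p = 0.0156, range 0.0156 to 0.719). ESR1 passed with the replicate block between both antibodies and trastuzumab alone (-0.36, adjusted p = 0.00765, range 0.00538 to 1). PGR passed with the replicate block in BT-TPR1 (0.45, adjusted p = 0.000369, range 2.05e-05 to 0.22). The ESR1 call with both antibodies ended with only the groups compared (adjusted p = 0.0576), range 8e-07 to 0.0576. The ESR1 call in BT-TPR1 ended scaled by library size alone (adjusted p = 0.0838), range 2.94e-06 to 0.0838. The PGR call with trastuzumab ended without untreated replicate 1, 2 or 3 (adjusted p = 0.136, 0.0992 and 0.0592), without trastuzumab replicate 2 or 3 (0.132 and 0.211), without trastuzumab plus pertuzumab replicate 2 (0.0566), without BT-TR1 replicate 2 or 3 (0.0508 and 0.0515), without BT-TR2 replicate 2 or 3 (0.0578 and 0.0555), without BT-TPR1 replicate 1, 2 or 3 (0.0529, 0.053 and 0.0542), without BT-TPR2 replicate 2 or 3 (0.0526 and 0.053), scaled by library size alone (0.132), in limma (0.0556), with only the groups compared (0.137) or with the GC correction (0.12), range 9.09e-06 to 0.211.

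In that order of groups too, PIK3CA, a catalytic subunit of PI3-kinase, stood at 20.2 ± 3.24, 24.1 ± 4.17, 24.9 ± 4.74, 30.8 ± 4.70, 25.5 ± 3.83, 28.2 ± 3.56 and 27.2 ± 4.52 CPM and rose in BT-TR1 (0.60 ± 0.19), with other changes between 0.25 and 0.48 that did not pass. PIK3CA passed with the replicate block with trastuzumab (0.25, adjusted p = 0.0343, range 0.0236 to 0.758), with both antibodies (0.30, adjusted p = 0.0108, range 0.0108 to 0.707), in BT-TR2 (0.33, adjusted p = 0.00339, range 0.00339 to 0.484), in BT-TPR1 (0.49, adjusted p = 7.8e-05, range 7.8e-05 to 0.218) and in BT-TPR2 (0.43, adjusted p = 0.000243, range 0.000243 to 0.287). CCND1, encoding cyclin D1, stood at 292 ± 32.6, 277 ± 21.8, 296 ± 16.0, 293 ± 21.6, 253 ± 9.36, 241 ± 10.1 and 226 ± 18.4 CPM and fell in BT-TPR1 (-0.28 ± 0.10) and BT-TPR2 (-0.37 ± 0.10). With both antibodies its change was 0.02 ± 0.10, adjusted p = 0.938, and its sign turned when single libraries were left out, but with the GC correction and replicate block it was 0.42 (adjusted p = 0.00128, range 0.00128 to 1). Its changes that did not pass lay between -0.21 and 0.02. With the GC correction its BT-TR1 value was 1.07 (adjusted p = 0.00135, range 2.47e-09 to 1). MKI67, a proliferation marker, stood at 144 ± 34.6, 80.1 ± 22.3, 73.7 ± 6.83, 193 ± 42.7, 139.9 ± 18.3, 133 ± 17.4 and 135 ± 18.1 CPM, with changes in the pools between -0.12 and 0.42 that did not pass. MKI67 passed with the replicate block in BT-TR1 (0.43, adjusted p = 0.000692, range 0.000692 to 0.812). The PIK3CA call in BT-TR1 ended without untreated replicate 1 (adjusted p = 0.0699), without BT-TR1 replicate 3 (0.0713), scaled by library size alone (0.0504), with the GC correction (0.117) or with the GC correction and replicate block (0.0616), range 3e-06 to 0.117. The CCND1 call in BT-TPR1 ended without untreated replicate 1 or 2 (adjusted p = 0.295 and 0.0656), without trastuzumab replicate 1 or 2 (0.0596 and 0.0811), without trastuzumab plus pertuzumab replicate 1 (0.0681), without BT-TR1 replicate 1, 2 or 3 (0.0638, 0.0802 and 0.0784), without BT-TR2 replicate 2 or 3 (0.0541 and 0.0501), without BT-TPR1 replicate 1, 2 or 3 (0.0678, 0.0951 and 0.131), without a filter (0.199), scaled by library size alone (0.494), with only the groups compared (0.127), with replicates 2 and 3 alone (0.0937), with the GC correction (0.957) or with the GC correction and replicate block (0.805), range 0.0117 to 0.957. The CCND1 call in BT-TPR2 ended without untreated replicate 1 (adjusted p = 0.0757), without a filter (0.0603), scaled by library size alone (0.133), with only the groups compared (0.106), with replicates 2 and 3 alone (0.06), with the GC correction (0.866, at a log2 fold change of 0.06) or with the GC correction and replicate block (0.879, at a log2 fold change of 0.02), range 0.00113 to 0.879.

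PPP1R1B, a phosphatase regulator encoded beside ERBB2 on chromosome 17 (ENSG00000131771.13, chromosome 17, 39626740 to 39636626), stood in the same order of groups at 2.26 ± 0.325, 2.02 ± 0.659, 3.44 ± 0.360, 23.6 ± 2.95, 33.3 ± 1.36, 96.3 ± 3.93 and 79.2 ± 6.73 CPM. It rose with both antibodies against untreated cells (0.59 ± 0.18) and against trastuzumab alone (0.78 ± 0.18), and in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (3.38 ± 0.17, 3.87 ± 0.17, 5.40 ± 0.18 and 5.12 ± 0.17). With trastuzumab its change (-0.18 ± 0.19, adjusted p = 0.619) did not pass. Its isoforms, which include a truncated form, could not be separated in counts per gene. The PPP1R1B call with both antibodies ended without untreated replicate 1 or 2 (adjusted p = 0.0843 and 0.104), without trastuzumab plus pertuzumab replicate 1, 2 or 3 (0.0855, 0.0707 and 0.0638), without a filter (0.0508), with only the groups compared (0.122), with replicates 2 and 3 alone (0.0633) or with thinning (0.223), range 0.0097 to 0.223. The PPP1R1B call between both antibodies and trastuzumab alone ended without untreated replicate 1 or 3 (adjusted p = 0.0511 and 0.0504), without trastuzumab replicate 2 or 3 (0.226 and 0.338), without trastuzumab plus pertuzumab replicate 1, 2 or 3 (0.218, 0.141 and 0.0876), without BT-TR1 replicate 2 (0.0592), without BT-TR2 replicate 1, 2 or 3 (0.0598, 0.0555 and 0.0676), without BT-TPR1 replicate 1, 2 or 3 (0.0547, 0.0577 and 0.0694), without BT-TPR2 replicate 2 or 3 (0.0522 and 0.0674) or with only the groups compared (0.516), range 0.00445 to 0.516.

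**Figure D2:**
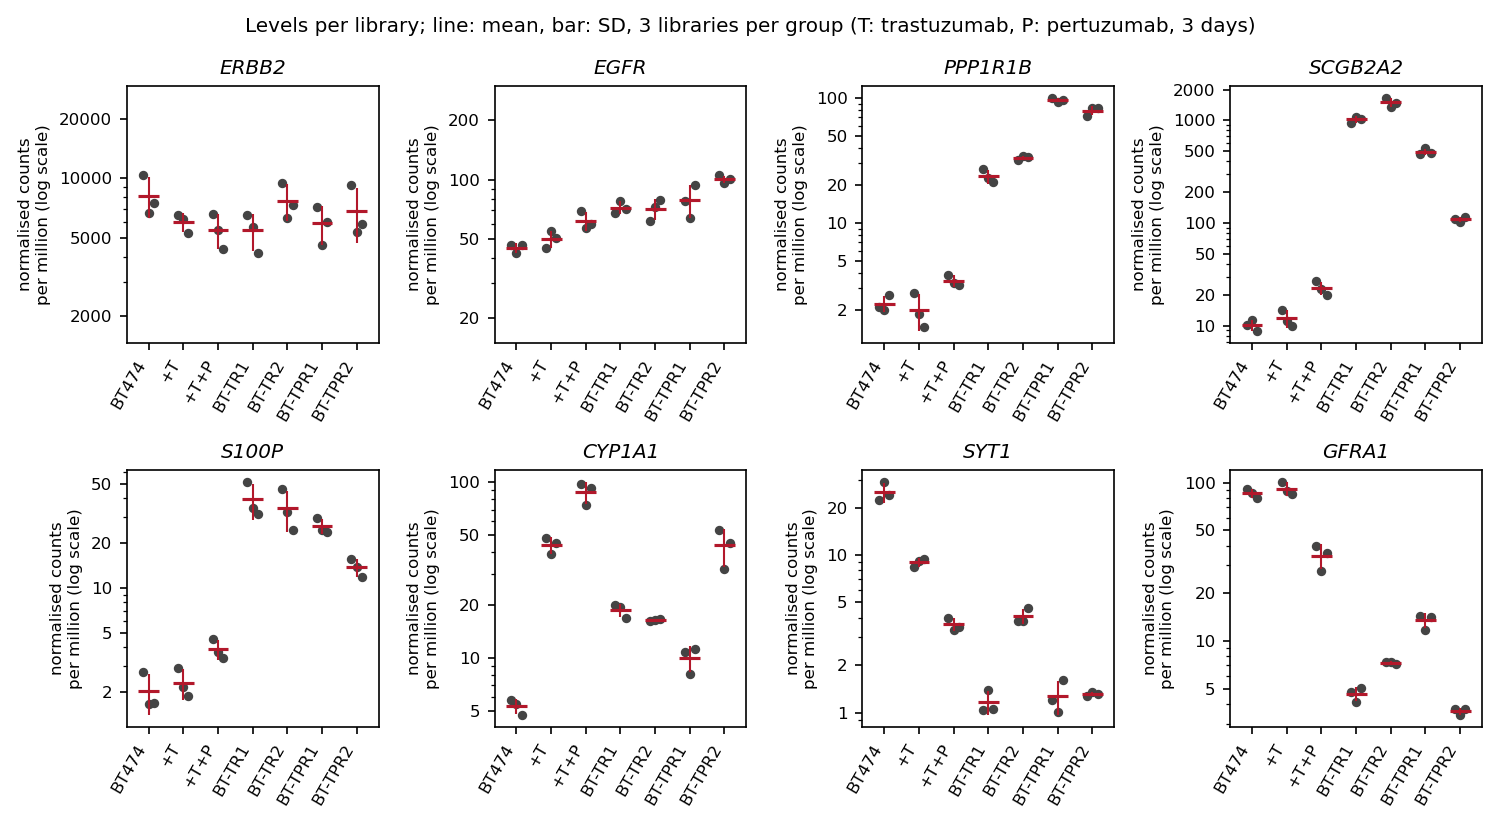
Scaled read counts (CPM, y axis, log scale) of 8 genes in the 7 groups (x axis). Points are the 3 libraries of a group, and lines are the mean ± SD. PPP1R1B stood at 2.26 ± 0.325 CPM in untreated cells and 96.3 ± 3.93 CPM in BT-TPR1.

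After 3 days of trastuzumab, 32 of 38 Mitosis, 7 of 39 DNA replication, 15 of 25 Cholesterol synthesis and 7 of 19 Fatty acid synthesis genes fell, and 8 of 23 p53 targets and 6 of 28 FOXO and PI3K-repressed genes rose. Camera called each of these lists, and of the calls the last was lost (adjusted p = 0.0663 with an estimated correlation). Changes are log2 fold changes ± standard error, taken from edgeR's quasi-likelihood F. The largest rises were in CYP1A1, a cytochrome P450 enzyme induced through the aryl hydrocarbon receptor (3.05 ± 0.18, ENSG00000140465.13, chromosome 15, 74719542 to 74725610), CRYM, a thyroid hormone binding protein (1.66 ± 0.13), MXI1, an antagonist of MYC (1.62 ± 0.24), SOCS2-AS1 (1.56 ± 0.16), RAI2 (1.54 ± 0.17) and LINC01411 (1.53 ± 0.21). The largest falls were in CYP51A1, a sterol demethylase (-2.30 ± 0.51, ENSG00000001630.15, chromosome 7, 92112151 to 92134803), the DNA helicase gene PIF1 (-2.15 ± 0.28), the protocadherin gene PCDH7 (-1.92 ± 0.21), the Wnt receptor gene FZD8 (-1.58 ± 0.32), the kinetochore motor gene CENPE (-1.56 ± 0.34) and SYT1, a calcium sensor of vesicle release (-1.48 ± 0.14). The libraries' strandedness was not stated, so counts for the antisense gene SOCS2-AS1 could hold reads from the other strand. The CENPE call with trastuzumab ended without untreated replicate 2 (adjusted p = 0.0688) or without trastuzumab replicate 1 (0.0528), range 1.75e-18 to 0.0688.

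Of the Mitosis list, 32 of 38 fell (37 adjusted over the list alone). Mitosis had a camera adjusted p of 1.34e-53, and adjusted p = 0.00215 with an estimated correlation. It was led by CENPE (-1.56 ± 0.34) and HMMR (-1.47 ± 0.26). MKI67 changed by -0.85 ± 0.21. For DNA replication, 7 of 39 fell (10 adjusted over the list alone). DNA replication had a camera adjusted p of 1.15e-07, and adjusted p = 0.00841 with an estimated correlation. The largest change was in UHRF1 (-0.94 ± 0.22). Among Cholesterol synthesis genes, 15 of 25 fell (19 adjusted over the list alone). Cholesterol synthesis had a camera adjusted p of 3.33e-17, and adjusted p = 0.0123 with an estimated correlation. First was CYP51A1 (-2.30 ± 0.51). Among Fatty acid synthesis genes, 7 of 19 fell (10 adjusted over the list alone). Fatty acid synthesis had a camera adjusted p of 4.9e-08, and adjusted p = 0.0229 with an estimated correlation. Its leader was ELOVL6 (-1.06 ± 0.13). Of FOXO and PI3K-repressed genes, 6 of 28 rose (12 adjusted over the list alone). FOXO and PI3K-repressed had a camera adjusted p of 2.64e-05, and adjusted p = 0.0663 with an estimated correlation. The largest were in IRS2 (1.003 ± 0.20) and PIK3IP1 (0.98 ± 0.18), the first an insulin receptor substrate gene. Of p53 targets, 8 of 23 rose (9 adjusted over the list alone). p53 targets had a camera adjusted p of 4.11e-09, and adjusted p = 0.00678 with an estimated correlation. These were led by FAS (2.72 ± 0.49) and CDKN1A (1.40 ± 0.27), a death receptor and a cell cycle inhibitor gene. The CENPE call with trastuzumab ended without untreated replicate 2 (adjusted p = 0.0688) or without trastuzumab replicate 1 (0.0528), range 1.75e-18 to 0.0688. The MKI67 call with trastuzumab ended without untreated replicate 2 or 3 (adjusted p = 0.0964 and 0.0645), without trastuzumab replicate 1 or 3 (0.0915 and 0.0567), scaled by library size alone (0.0551) or with only the groups compared (0.0958), range 1.18e-06 to 0.0964. The UHRF1 call with trastuzumab ended without untreated replicate 1 (adjusted p = 0.0635) or without trastuzumab replicate 3 (0.054), range 5.24e-06 to 0.0635. The IRS2 call with trastuzumab ended with thinning (adjusted p = 0.119), range 6.42e-05 to 0.119. The CDKN1A call with trastuzumab ended with only the groups compared (adjusted p = 0.052), range 1.71e-09 to 0.052.

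In total 1321 genes passed the test for trastuzumab, of which 654 rose and 667 fell. Of all genes, 4629 passed with replicate number as a block. Leaving out untreated replicate 2, trastuzumab replicate 2 or trastuzumab replicate 3 gave 659, 879 and 597 genes. The 12 genes with the largest changes were chosen among genes whose 3 treated and 3 untreated libraries did not overlap, which by chance holds for 10% of genes.

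With both antibodies for 3 days, 36 of 38 Mitosis and 17 of 25 Cholesterol synthesis genes fell and 10 of 23 p53 targets rose, and 6 of 18 genes of the Heat shock and dissociation stress list and 10 of 28 Other receptor tyrosine kinases and ligands fell. Camera called each of these lists, and of the calls the last was lost (adjusted p = 0.179 with an estimated correlation). CYP1A1 rose by 4.05 ± 0.19, C10orf10 by 3.98 ± 0.19 (ENSG00000165507.8, chromosome 10, 44970981 to 44978810), the apocrine secretory protein gene PIP by 2.34 ± 0.24, the iron reductase gene CYBRD1 by 2.30 ± 0.16, FGD5 by 2.23 ± 0.20 and TNFSF15, a TNF family ligand gene, by 2.06 ± 0.16. The largest falls were in PCDH7 (-3.69 ± 0.23), EGR1, an immediate early transcription factor (-2.90 ± 0.38, ENSG00000120738.7, chromosome 5, 138465490 to 138469315), SYT1 (-2.80 ± 0.16), the protocadherin gene PCDH19 (-2.53 ± 0.16), SOX2, a stem cell transcription factor (-2.35 ± 0.28), and the mucin gene MUC19 (-2.30 ± 0.32). MKI67 changed by -0.97 ± 0.21.

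Of the Mitosis list, 36 of 38 fell (38 adjusted over the list alone). Mitosis had a camera adjusted p of 1.4e-48, and adjusted p = 0.00348 with an estimated correlation. Its largest changes were in CENPE (-1.64 ± 0.34) and HMMR (-1.55 ± 0.26). Among Cholesterol synthesis genes, 17 of 25 fell (20 adjusted over the list alone). Cholesterol synthesis had a camera adjusted p of 1.85e-10, and adjusted p = 0.0438 with an estimated correlation. The largest was CYP51A1 (-2.06 ± 0.50). For DNA replication, 7 of 39 fell (10 adjusted over the list alone). DNA replication had a camera adjusted p of 6.38e-05, and adjusted p = 0.0403 with an estimated correlation. At the top was CDT1 (-1.06 ± 0.32). Of FOXO and PI3K-repressed genes, 12 of 28 rose (14 adjusted over the list alone). FOXO and PI3K-repressed had a camera adjusted p of 5.2e-08, and adjusted p = 0.0348 with an estimated correlation. The leading members were IRS2 (1.51 ± 0.20) and PIK3IP1 (1.23 ± 0.18). Of p53 targets, 10 of 23 rose (15 adjusted over the list alone). p53 targets had a camera adjusted p of 4.94e-09, and adjusted p = 0.00783 with an estimated correlation. The largest change was that of FAS (2.72 ± 0.49). Of the Heat shock and dissociation stress list, 6 of 18 fell (10 adjusted over the list alone). Heat shock and dissociation stress had a camera adjusted p of 7.79e-06, and adjusted p = 0.0438 with an estimated correlation. Immediate early genes rather than chaperones led, namely EGR1 (-2.90 ± 0.38) and FOS (-1.82 ± 0.24). Of Other receptor tyrosine kinases and ligands, 10 of 28 fell (11 adjusted over the list alone). Other receptor tyrosine kinases and ligands had a camera adjusted p of 7.79e-06, and adjusted p = 0.179 with an estimated correlation. Its largest changes, led by a GDNF family ligand gene, were in ARTN (2 counts against 25), EPHA3 (-2.36 ± 0.35) and NTRK3 (-1.54 ± 0.32). Of ERK pathway output genes, 9 of 22 rose (9 adjusted over the list alone). ERK pathway output had a camera adjusted p of 0.0141, and adjusted p = 0.179 with an estimated correlation. By size, EGR1 (-2.90 ± 0.38) and FOS (-1.82 ± 0.24) came first, and 4 members fell. The CYP51A1 call with both antibodies ended without trastuzumab plus pertuzumab replicate 3 (adjusted p = 0.0676), range 1.93e-14 to 0.0676. The CDT1 call with both antibodies ended without untreated replicate 1 (adjusted p = 0.167), without trastuzumab plus pertuzumab replicate 2 or 3 (0.0695 and 0.169), with only the groups compared (0.0504) or with thinning (0.0979), range 6e-07 to 0.169. The NTRK3 call with both antibodies ended with thinning (adjusted p = 0.0531), range 6.09e-05 to 0.0531. The ERK pathway output call with both antibodies ended with only the groups compared (adjusted p = 0.0619), range 0.000367 to 0.0619.

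In total 2190 genes passed for both antibodies, of which 1128 rose and 1062 fell. The replicate numbers did not pair these libraries, through replicate 2 alone, and with replicate number as a block 5750 passed. Leaving out replicate 2 or 3 with both antibodies gave 1325 and 1104 genes. Of the genes called for trastuzumab, 522 rose and 536 fell with both antibodies too, against 41.8 and 40.1 if the calls were independent, and 3 went the opposite way, against 82. Both comparisons used the same untreated libraries. In 10 simulations of unchanged groups 0 genes were shared, but such groups give almost no calls, so this decides nothing.

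Against trastuzumab alone, 8 of 22 ERK pathway output genes, among them ETS transcription factors and feedback inhibitors, were higher with pertuzumab added and 2 lower, and 3 of 30 Estrogen receptor targets were lower. Camera called both lists, also with an estimated correlation. The largest rises against trastuzumab alone were in ETV5 (1.84 ± 0.12, ENSG00000244405.7, chromosome 3, 186046308 to 186110318), the integrin gene ITGB6 (1.58 ± 0.16), ETV4 (1.55 ± 0.23), PIP (1.51 ± 0.23), FGD5 (1.49 ± 0.19) and the matrix protein gene TGFBI (1.46 ± 0.17). The largest falls were in EGR1 (-2.00 ± 0.38), PCDH19 (-1.76 ± 0.16), MAT1A, a methionine adenosyltransferase (-1.64 ± 0.18), GFRA1 (-1.41 ± 0.12), SYT1 (-1.31 ± 0.15) and CBLN2 (-1.22 ± 0.13). Of ERK pathway output genes, 8 of 22 rose (10 adjusted over the list alone). ERK pathway output had a camera adjusted p of 1.14e-18, and adjusted p = 0.000259 with an estimated correlation. In order of size, the first members were EGR1 (-2.00 ± 0.38), ETV5 (1.84 ± 0.12), ETV4 (1.55 ± 0.23), FOS (-1.33 ± 0.24) and SPRED1 (1.05 ± 0.14). Of Estrogen receptor targets, 3 of 30 fell (10 adjusted over the list alone). Estrogen receptor targets had a camera adjusted p of 1.21e-13, and adjusted p = 0.000622 with an estimated correlation. The members called were PGR (-0.77 ± 0.17), CXCL12 (-0.62 ± 0.10) and GREB1 (-0.52 ± 0.11). ERBB4 changed by -0.79 ± 0.15. The ETV4 call between both antibodies and trastuzumab alone ended with thinning (adjusted p = 0.0798), range 2.57e-09 to 0.0798. The EGR1 call between both antibodies and trastuzumab alone ended without trastuzumab replicate 2 (adjusted p = 0.0773), without trastuzumab plus pertuzumab replicate 1 or 3 (0.0703 and 0.0681) or with only the groups compared (0.124), range 8.18e-21 to 0.124. The FOS call between both antibodies and trastuzumab alone ended without trastuzumab replicate 2 (adjusted p = 0.0534), without trastuzumab plus pertuzumab replicate 1 (0.0563) or with only the groups compared (0.0513), range 3.21e-05 to 0.0563. The PGR call between both antibodies and trastuzumab alone ended without trastuzumab replicate 2 or 3 (adjusted p = 0.178 and 0.215), without trastuzumab plus pertuzumab replicate 1 or 2 (0.234 and 0.133), without BT-TR2 replicate 2 (0.05), scaled by library size alone (0.19), with only the groups compared (0.277) or with the GC correction (0.513), range 7.42e-06 to 0.513. The CXCL12 call between both antibodies and trastuzumab alone ended with only the groups compared (adjusted p = 0.0651) or with the GC correction (0.0551), range 1.34e-08 to 0.0651. The GREB1 call between both antibodies and trastuzumab alone ended without trastuzumab replicate 1 or 2 (adjusted p = 0.0768 and 0.106), without trastuzumab plus pertuzumab replicate 1, 2 or 3 (0.0592, 0.136 and 0.0876), with only the groups compared (0.112) or with thinning (0.0536), range 7.42e-05 to 0.136. The ERBB4 call between both antibodies and trastuzumab alone ended without trastuzumab replicate 1 (adjusted p = 0.0514), without trastuzumab plus pertuzumab replicate 2 or 3 (0.0965 and 0.0876), with only the groups compared (0.109) or with thinning (0.0593), range 0.000114 to 0.109.

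In total 153 genes passed between both antibodies and trastuzumab alone, of which 86 rose and 67 fell, while 388 passed with replicate number as a block. Leaving out trastuzumab replicate 2 or 3, or replicate 1 or 2 with both antibodies, gave 96, 82, 82 and 87 genes.

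In the pools selected for trastuzumab resistance, SCGB2A2, which encodes mammaglobin, rose in BT-TR1 and BT-TR2 by 6.65 ± 0.17 and 7.20 ± 0.18 (ENSG00000110484.6, chromosome 11, 62270155 to 62273156), from 10.2 ± 1.29 CPM in untreated cells to 1021 ± 72.0 and 1495 ± 159 CPM. GLYATL3 stood at 0.0496 ± 0.0518 CPM in untreated cells, 3 counts in all, against 12.03 ± 0.919 and 13.1 ± 1.07 CPM. S100P rose by 4.28 ± 0.27 and 4.08 ± 0.27, LINC01468 by 5.06 ± 0.31 and 3.90 ± 0.31, NCMAP by 4.89 ± 0.34 and 3.76 ± 0.34, and AZGP1 by 3.74 ± 0.23 and 4.20 ± 0.23. The chemokine gene CXCL14 stood at 30.4 ± 3.75 CPM in untreated cells against 0.0290 ± 0.0502 CPM in BT-TR1, 1 count in all, and 0.402 ± 0.320 CPM in BT-TR2 (log2 fold change -6.26 ± 0.34). PCDH7 changed by -5.69 ± 0.31 and -4.22 ± 0.25, GFRA1 by -4.22 ± 0.15 and -3.55 ± 0.14, P2RY10 by -4.26 ± 0.23 and -3.20 ± 0.20, the metalloproteinase gene ADAMTS1 by -3.86 ± 0.18 and -3.04 ± 0.16, and PCDH19 by -4.37 ± 0.20 and -3.02 ± 0.17.

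In BT-TR1 7693 genes passed, of which 3752 rose and 3941 fell, and in BT-TR2 4387, of which 2245 rose and 2142 fell. With replicate number as a block, 10145 and 8076 passed. Without it, 2979 went the same way in both pools (1593 rose and 1386 fell, but 1765 and 2284 with the GC correction), and 5609 did with the block. The pools' changes correlated at 0.749 against 0.454 for unchanged groups with shared controls in 10 simulations. With the GC correction 4880 of the 7693 BT-TR1 genes were called in the same direction.

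The pools resistant to both antibodies had higher PPP1R1B, which ranked first by the smaller of the pools' changes (5.40 ± 0.18 in BT-TPR1 and 5.12 ± 0.17 in BT-TPR2). SCGB2A2 rose by 5.61 ± 0.16 and 3.42 ± 0.15, the gel-forming mucin gene MUC5AC by 4.99 ± 0.36 and 3.22 ± 0.37, vitronectin gene VTN by 3.19 ± 0.34 and 3.44 ± 0.34, S100A4 by 2.92 ± 0.19 and 2.96 ± 0.19, and S100P by 3.68 ± 0.27 and 2.77 ± 0.27. SYT1 changed by -4.30 ± 0.18 and -4.25 ± 0.17, P2RY10 by -3.93 ± 0.21 and -3.84 ± 0.20, PCDH7 by -4.40 ± 0.25 and -3.72 ± 0.24, the neuroserpin gene SERPINI1 by -4.01 ± 0.22 and -3.68 ± 0.22 (ENSG00000163536.12, chromosome 3, 167735243 to 167825568), the anthrax toxin receptor gene ANTXR1 by -3.54 ± 0.15 and -3.58 ± 0.15, and FSTL1 by -3.95 ± 0.17 and -3.43 ± 0.16. In BT-TPR1 4815 genes passed (2280 rose and 2535 fell), and in BT-TPR2 5575 (2746 rose and 2829 fell). With replicate number as a block, 8364 and 9019 passed. Without it, 3545 went the same way in both pools (1728 rose and 1817 fell), and 6458 did with the block. The changes correlated at 0.825 against 0.486 from shared controls alone. Leaving out BT-TPR1 replicate 2 gave 3156 genes in BT-TPR1, and leaving out BT-TPR2 replicate 2 gave 3665 in BT-TPR2. Scaled by library size alone, rises made up 63.15% of BT-TPR1 calls and 61.52% of calls shared by both pools, with the BT-TPR1 median of all genes shifted by 0.143 (log2).

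In each pool, 14 to 20 of 30 Estrogen receptor targets, 13 to 19 of 28 Other receptor tyrosine kinases and ligands, 6 to 10 of 15 Notch pathway genes and 10 to 22 of 39 DNA replication genes fell, and 6 to 13 of 25 genes of the 20q13 amplicon and 13 to 19 of 38 Oxidative phosphorylation genes rose. Camera called each list in each pool. Only the calls of Estrogen receptor targets in BT-TR1 and BT-TR2 and of DNA replication in BT-TR1 held, and the others were lost (adjusted p = 0.0626 to 0.894 with an estimated correlation). Of Estrogen receptor targets, 20, 18, 14 and 17 of 30 fell in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (20, 23, 15 and 18 adjusted over the list alone). Estrogen receptor targets had camera adjusted p of 5.77e-09, 1.4e-10, 0.000599 and 1.63e-05, and adjusted p = 0.0103, 0.00362, 0.188 and 0.0714 with an estimated correlation. The largest member changes were CTSD (-2.39 ± 0.44) in BT-TR1, AREG (-1.61 ± 0.23) in BT-TR2, STC2 (-2.00 ± 0.12) in BT-TPR1 and IL6ST (-1.99 ± 0.15) in BT-TPR2. Of Other receptor tyrosine kinases and ligands, 19, 14, 13 and 14 of 28 fell in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (21, 15, 13 and 14 adjusted over the list alone). Other receptor tyrosine kinases and ligands had camera adjusted p of 1.99e-10, 2.22e-10, 2.42e-05 and 2.92e-06, and adjusted p = 0.0626, 0.128, 0.258 and 0.181 with an estimated correlation. GFRA1 came first in BT-TR1 (-4.22 ± 0.15), BT-TR2 (-3.55 ± 0.14), BT-TPR1 (-2.67 ± 0.13) and BT-TPR2 (-4.57 ± 0.15). Of Notch pathway genes, 10, 7, 7 and 6 of 15 fell in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (11, 8, 7 and 6 adjusted over the list alone). Notch pathway genes had camera adjusted p of 0.00242, 0.00306, 0.0074 and 0.00113, and adjusted p = 0.432, 0.345, 0.303 and 0.265 with an estimated correlation. First by size was NOTCH1 (-2.41 ± 0.37) in BT-TR1, JAG1 (-2.06 ± 0.20) in BT-TR2, JAG1 (-2.04 ± 0.20) in BT-TPR1 and MAML2 (-3.62 ± 0.51) in BT-TPR2. For DNA replication, 22, 10, 13 and 15 of 39 fell in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (22, 10, 14 and 15 adjusted over the list alone). DNA replication had camera adjusted p of 5.34e-06, 0.00442, 0.00878 and 0.00355, and adjusted p = 0.0366, 0.203, 0.247 and 0.181 with an estimated correlation. Top members were POLD1 (-1.88 ± 0.43) in BT-TR1 and UHRF1 in BT-TR2 (-0.90 ± 0.23), BT-TPR1 (-0.83 ± 0.23) and BT-TPR2 (-1.34 ± 0.23). Of the 20q13 amplicon, a region often gained in breast cancer, 13, 6, 9 and 8 of 25 rose in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (14, 6, 10 and 9 adjusted over the list alone). 20q13 amplicon had camera adjusted p of 0.00164, 0.0111, 0.0215 and 0.00479, and adjusted p = 0.0626, 0.23, 0.247 and 0.181 with an estimated correlation. Its largest changes were BCAS1 (2.01 ± 0.13) in BT-TR1, BCAS1 (1.38 ± 0.12) in BT-TR2, SALL4 (-1.66 ± 0.43) in BT-TPR1 and BCAS4 (1.35 ± 0.16) in BT-TPR2. Of Oxidative phosphorylation genes, 13, 16, 16 and 19 of 38 rose in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (13, 20, 16 and 20 adjusted over the list alone). Oxidative phosphorylation had camera adjusted p of 0.0104, 0.000385, 0.000599 and 5.91e-05, and adjusted p = 0.894, 0.469, 0.363 and 0.306 with an estimated correlation. NDUFV1 led in BT-TR1 (-1.03 ± 0.25), and COX6B1 in BT-TR2 (0.997 ± 0.14), BT-TPR1 (0.70 ± 0.13) and BT-TPR2 (1.06 ± 0.14). The lists described were picked among the called ones after their values were seen. The UHRF1 call in BT-TPR1 ended without untreated replicate 1 (adjusted p = 0.065) or without BT-TPR1 replicate 3 (0.0507), range 1.37e-05 to 0.065. The 20q13 amplicon call in BT-TPR1 ended with only the groups compared (adjusted p = 0.0512), range 0.000112 to 0.0512. The SALL4 call in BT-TPR1 ended with thinning (adjusted p = 0.108), range 3.8e-06 to 0.108. The Oxidative phosphorylation call in BT-TR1 ended without BT-TR1 replicate 1 (adjusted p = 0.089), range 4.1e-05 to 0.089.

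In BT-TR2, BT-TPR1 and BT-TPR2, 13 to 16 of 25 Cholesterol synthesis genes, 10 to 15 of 21 Endoplasmic reticulum chaperones and 3 to 8 of 11 MHC class I presentation genes fell. Camera called each of these lists in each, and all of the calls were lost (adjusted p = 0.181 to 0.553 with an estimated correlation). In BT-TR1, 12, 6 and 3 of them fell and the lists were not called (camera adjusted p = 0.114, 0.497 and 0.552), though Cholesterol synthesis passed there under 6 of 34 alternatives, the replicate block among them (adjusted p = 0.0326, range 0.00558 to 0.159). Of Cholesterol synthesis genes, 13, 16 and 13 of 25 fell in BT-TR2, BT-TPR1 and BT-TPR2 (14, 19 and 13 adjusted over the list alone). Cholesterol synthesis had camera adjusted p of 0.000876, 5.98e-06 and 0.000332, and adjusted p = 0.36, 0.247 and 0.287 with an estimated correlation. CYP51A1 led in BT-TR2 (-1.61 ± 0.49) and BT-TPR2 (-2.19 ± 0.51). Of Endoplasmic reticulum chaperones, 10, 15 and 13 of 21 fell in BT-TR2, BT-TPR1 and BT-TPR2 (13, 15 and 14 adjusted over the list alone). Endoplasmic reticulum chaperones had camera adjusted p of 0.00506, 2.27e-06 and 0.000242, and adjusted p = 0.553, 0.247 and 0.302 with an estimated correlation. Members led with HYOU1 (-0.86 ± 0.12) in BT-TR2, CRELD2 (-1.28 ± 0.29) in BT-TPR1 and CALR (-1.50 ± 0.16) in BT-TPR2. Of MHC class I presentation genes, 3, 8 and 6 of 11 fell in BT-TR2, BT-TPR1 and BT-TPR2 (6, 9 and 7 adjusted over the list alone). MHC class I presentation had camera adjusted p of 0.00952, 9.77e-05 and 0.00235, and adjusted p = 0.324, 0.188 and 0.181 with an estimated correlation. In front were ERAP2 (-1.36 ± 0.24) in BT-TR2, HLA-B (-1.86 ± 0.36) in BT-TPR1 and CALR (-1.50 ± 0.16) in BT-TPR2. Of Replication-dependent histones, 5, 7 and 7 of 19 rose in BT-TR2, BT-TPR1 and BT-TPR2 (9, 10 and 7 adjusted over the list alone). Replication-dependent histones had camera adjusted p of 0.0408, 9.77e-05 and 0.000759, and adjusted p = 0.694, 0.339 and 0.442 with an estimated correlation. The linker histone gene HIST1H1C led in BT-TPR1 (1.30 ± 0.20) and BT-TPR2 (1.40 ± 0.20). In BT-TPR1 against BT-TR1, BT-TPR1 against BT-TR2, BT-TPR2 against BT-TR1 and BT-TPR2 against BT-TR2, 12, 2, 10 and 3 members of Endoplasmic reticulum chaperones were lower, with camera adjusted p of 0.000409, 0.00362, 0.00581 and 0.108. In that order, 6, 1, 6 and 1 members of MHC class I presentation were lower, with camera adjusted p of 0.00284, 0.0583, 0.0377 and 0.404, 10, 2, 8 and 0 members of Cholesterol synthesis were lower, with camera adjusted p of 0.0144, 0.0837, 0.129 and 0.46, and 7, 3, 4 and 3 members of Replication-dependent histones were higher, with camera adjusted p of 0.00083, 0.0134, 0.00525 and 0.103. In BT-TPR1 against BT-TR2, MHC class I presentation and Cholesterol synthesis passed with the replicate block (adjusted p = 0.0286, range 0.028 to 0.269, and 0.0288, range 0.0205 to 0.368). In BT-TPR2 against BT-TR2, Replication-dependent histones passed under 6 of 34 alternatives, the median change going from 0.0256 to 0.70 without BT-TR2 replicate 1 (adjusted p = 2.59e-07, range 2.59e-07 to 0.444), and Endoplasmic reticulum chaperones under 3. Cholesterol synthesis did in BT-TPR2 against BT-TR1 under 2. None of these differences held (adjusted p = 0.213 to 0.852 with an estimated correlation). Several genes, CALR among them, belong to more than 1 list. The CYP51A1 call in BT-TR2 ended without untreated replicate 1 or 2 (adjusted p = 0.072 and 0.061) or without BT-TR2 replicate 2 or 3 (0.0919 and 0.0913), range 1.32e-09 to 0.0919. The Replication-dependent histones call in BT-TR2 ended without untreated replicate 1 (adjusted p = 0.0509), without BT-TR2 replicate 1 (0.503), with the strict filter (0.0883), with only the groups compared (0.0731), with replicates 2 and 3 alone (0.597), with the GC correction (0.0815), with thinning (0.0916) or in fry (0.0909), range 0.000484 to 0.597. The MHC class I presentation call in BT-TPR2 against BT-TR1 ended without BT-TPR2 replicate 2 or 3 (adjusted p = 0.111 and 0.0876) or with the strict filter (0.0577), range 0.00364 to 0.111. The Cholesterol synthesis call in BT-TPR1 against BT-TR1 ended without BT-TPR1 replicate 2 (adjusted p = 0.111), range 0.00113 to 0.111. The Replication-dependent histones call in BT-TPR1 against BT-TR2 ended without BT-TR2 replicate 2 or 3 (adjusted p = 0.212 and 0.12), without BT-TPR1 replicate 1 (0.16) or in fry (0.234), range 1.65e-09 to 0.234.

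**Figure D3:**
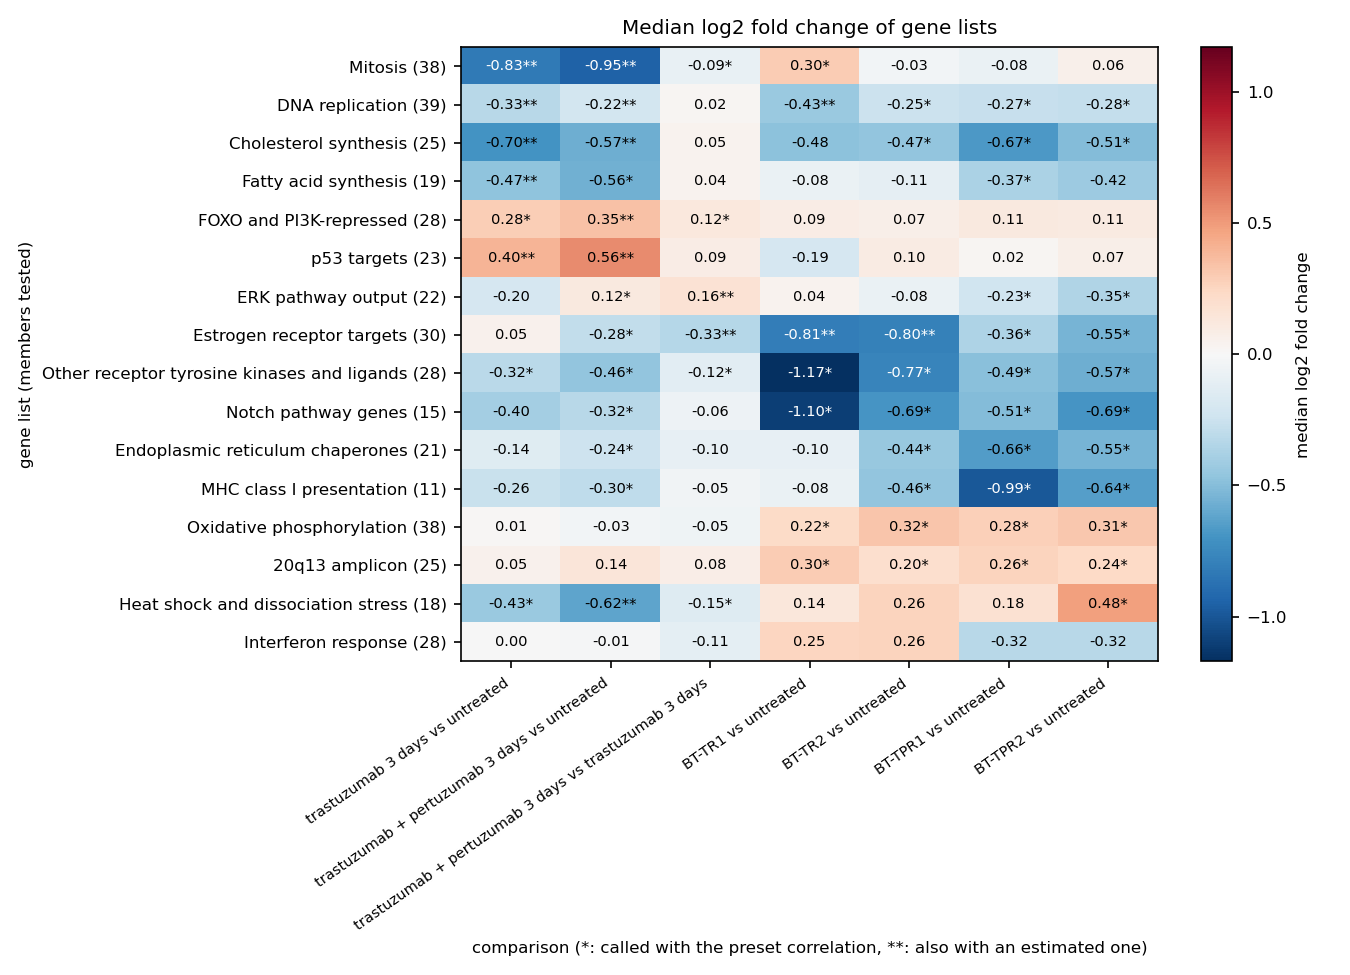
Median log2 fold change of the members of 16 gene lists (y axis) in 7 comparisons (x axis), as colour. One star marks a camera call at the preset correlation and a double star a call that held with an estimated correlation as well. Mitosis fell after 3 days of antibody, with medians of -0.83 and -0.95.

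In all 4 pools, 1803 genes changed the same way, of which 957 rose and 846 fell, but 1083 and 1426 with the GC correction. Ranked by the smallest change over the pools, the rises were led by SCGB2A2, PPP1R1B, MUC5AC, S100P, the pseudogene ASS1P11 (2.25 to 3.28) and S100A4 (2.21 to 2.96). The falls were led by P2RY10, ADAMTS1 (-3.04 to -3.94), the neuroligin gene NLGN4X (-2.84 to -3.93), GFRA1 (-2.67 to -4.57), SYT1 (-2.62 to -4.42) and SERPINI1 (-2.58 to -4.01). Reads of ASS1P11 may be shared with its parent gene. Changes correlated at 0.615 against 0.455 from shared controls alone for BT-TR1 with BT-TPR1, and at 0.743 against 0.49 for BT-TR2 with BT-TPR2. Between the classes, 14 genes went opposite ways. With replicate number as a block, 3807 genes passed in all 4 pools.

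Between the classes, camera called the Interferon response list lower in each BT-TPR pool than in each BT-TR pool, the call of BT-TPR1 against BT-TR1 being lost (adjusted p = 0.0641 with an estimated correlation). Of the Interferon response list, 10, 10, 11 and 9 of 28 fell in BT-TPR1 against BT-TR1, BT-TPR1 against BT-TR2, BT-TPR2 against BT-TR1 and BT-TPR2 against BT-TR2 (10, 16, 13 and 13 adjusted over the list alone). Interferon response had camera adjusted p of 0.00284, 5.59e-06, 0.00525 and 5.89e-07, and adjusted p = 0.0641, 0.00138, 0.0309 and 0.000643 with an estimated correlation. Many of these genes stood near the floor. By size, the first member was IFIT2 (-3.09 ± 0.39) in BT-TPR1 against BT-TR1, OAS2 (-2.87 ± 0.66) in BT-TPR1 against BT-TR2, OAS2 (3 counts against 19) in BT-TPR2 against BT-TR1 and OAS2 (3 counts against 33) in BT-TPR2 against BT-TR2. IFIT1, an antiviral RNA-binding protein gene, stood at 1.152 ± 0.421 and 0.927 ± 0.0930 CPM in BT-TR1 and BT-TR2 against 0.145 ± 0.1001 and 0.202 ± 0.0264 CPM in BT-TPR1 and BT-TPR2, where its 3 libraries held 7 and 11 counts. OAS2, an RNA sensor gene, held 19 and 33 counts in the BT-TR pools against 4 and 3 in the BT-TPR pools, and 5 in untreated cells. The OAS2 call in BT-TPR1 against BT-TR2 ended without BT-TR2 replicate 3 (adjusted p = 0.0574) or without BT-TPR1 replicate 2 (0.0582), range 0.000962 to 0.0582.

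In total 424 genes differed the same way in all 4 comparisons of a BT-TPR pool with a BT-TR pool, of which 97 were higher in the BT-TPR pools and 327 lower, and 871 passed with replicate number as a block. The ranked rises were SLC44A5 (1.64 to 2.07), HGD, an enzyme of tyrosine breakdown (1.43 to 1.77), EFS (1.32 to 2.53), PPP1R1B (1.25 to 2.02), the transcription factor gene BHLHE40 (1.14 to 1.28) and VEGFB (1.06 to 1.76). The falls were NCMAP (-3.58 to -4.84), GLYATL3 (-2.54 to -5.97), GPX8, a peroxidase of the endoplasmic reticulum (-2.10 to -3.36), ANXA1 (-2.04 to -4.08), UGT3A2 (-2.00 to -2.59) and the receptor phosphatase gene PTPRM (-1.88 to -2.57).

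**Figure D4:**
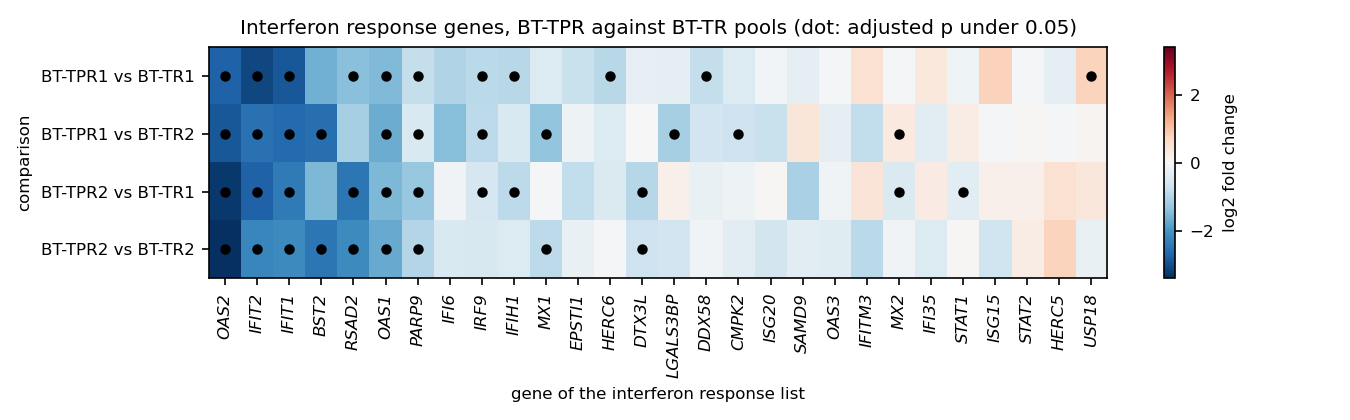
Log2 fold change (colour) of 28 interferon response genes (x axis) in the 4 comparisons of a BT-TPR pool with a BT-TR pool (y axis). Dots mark an adjusted p under 0.05 in edgeR's quasi-likelihood test. In BT-TPR1 against BT-TR2, 10 genes were lower and 1 was higher.

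Some changes after 3 days of antibody were also present in the resistant pools. For trastuzumab and both BT-TR pools, 345 genes went the same way (178 rose and 167 fell, against 59 and 52.4 if independent) and 91 the opposite way, against 111.6. The shared rises were led by CYP1A1, CRYM, BPIFB1 (1.28 ± 0.28 with trastuzumab), BCAS1 (1.14 ± 0.12), the cystatin gene CST1 (1.12 ± 0.26) and the autophagy gene GABARAPL1 (1.30 ± 0.13). The shared falls were led by PCDH7, SYT1, the axon guidance receptor gene ROBO1 (-1.41 ± 0.13), CXCL14 (-1.25 ± 0.23), NOTCH1 (-1.20 ± 0.33) and the zinc transporter gene SLC39A8 (-1.20 ± 0.15). For both antibodies and both BT-TPR pools, 698 genes went the same way (337 rose and 361 fell, against 110.4 and 109.3) and 145 the opposite way, against 220.1. Shared rises were led by MXI1 (1.77 ± 0.24 with both antibodies), VTN (1.57 ± 0.36), SCGB2A2 (1.20 ± 0.14), SNX30 (1.16 ± 0.18), VEGFB (1.12 ± 0.24) and CAMK2N1 (1.02 ± 0.12). Shared falls were led by PCDH7, SYT1, CXCL14 (-2.07 ± 0.24), ROBO1 (-1.83 ± 0.14), NCAM2 (-1.57 ± 0.13) and GABRE (-1.52 ± 0.23). The CST1 call with trastuzumab ended without untreated replicate 2 (adjusted p = 0.0714), without trastuzumab replicate 1 (0.0706) or with only the groups compared (0.0519), range 7.81e-07 to 0.0714. The NOTCH1 call with trastuzumab ended without untreated replicate 1 or 2 (adjusted p = 0.15 and 0.0565) or without trastuzumab replicate 1, 2 or 3 (0.0908, 0.0996 and 0.0938), range 9.13e-09 to 0.15. The VTN call with both antibodies ended with only the groups compared (adjusted p = 0.0504), range 2.23e-06 to 0.0504. The VEGFB call with both antibodies ended with only the groups compared (adjusted p = 0.0593), range 1.74e-06 to 0.0593.

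Each such overlap rests on the same untreated libraries. In 10 simulations of unchanged groups against shared controls, at most 1 gene was called the same way. Unchanged groups give almost no calls, so such counts cannot judge an overlap. The correlations across genes were 0.328, 0.284, 0.3 and 0.307 for trastuzumab with BT-TR1 and BT-TR2 and for both antibodies with BT-TPR1 and BT-TPR2, each below the value that shared controls alone gave (0.465, 0.491, 0.488 and 0.498). The covariances were 0.119, 0.0789, 0.099 and 0.108, against 0.0373, 0.037, 0.037 and 0.0371. With replicate number as a block, 1720 and 2376 genes were shared. Leaving out untreated replicate 2 or trastuzumab replicate 3 gave 131 and 145 genes shared with the BT-TR pools. Leaving out untreated replicate 2, or replicate 2 or 3 with both antibodies, gave 372, 376 and 354 genes shared with the BT-TPR pools. Rises made up 51.59% of the genes shared by trastuzumab and the BT-TR pools, 36.41% when scaled by library size alone and 34.51% with the GC correction.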

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

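The tests of gene length for the replicate 1 libraries, of GC content and depth for the shares of falls, and of windows by pool, with a cut of 0.3 or with single libraries left out were chosen only after the results were seen.

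The pools of a class differed from each other in edgeR's quasi-likelihood test, BT-TR2 from BT-TR1 in 3129 genes, of which 1701 were higher in BT-TR2. BT-TPR2 and BT-TPR1 differed in 609 genes, of which 289 were higher in BT-TPR2. Between BT-TR1 and BT-TR2, 14 genes were called in opposite directions against untreated cells, among them CD44, NUPR1, SLC6A14, ERAP2 and CREG1, chosen after their values were seen. Between BT-TPR1 and BT-TPR2 there were 19, among them PIP, EGR3, GRIK3, STS and CYP2B7P, chosen likewise. In all of these, the direct test between the pools passed as well.

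The replicate 1 libraries of the 7 groups deviated from their group means together, with a mean correlation across genes of 0.546 over 21 pairs of libraries. Genes are not independent replicates. After the GC correction the mean was 0.415, which excludes the GC trend that was removed as the whole cause. GC bias that the correction left was not tested. The mean correlation with transcript length was -0.0497, which argues against length. A shared day or batch of library preparation may account for it, but the labels give none, so it was not tested.

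Among called genes that changed 2-fold or more, 73.13%, 57.17%, 72.38% and 66.65% fell in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2. With all libraries thinned to the shallowest, the shares in BT-TR1, BT-TPR1 and BT-TPR2 were 74.94%, 71.75% and 67.3% (at least 69.79%, 65.27% and 60.4% with any 1 library left out), which argues against depth. After the GC correction these 3 shares were 64.41%, 72.39% and 65.08%, but 48.53%, 71.04% and 59.23% with the median of its shifts set to 0 and 56.11%, 71.82% and 63.08% with the median change of all genes set to 0. This excludes the GC trend that was removed as the whole cause in BT-TPR1 (at least 65.33% with 1 library left out). In BT-TR1 and BT-TPR2 GC content cannot be told apart from other causes, since the share moved with the centring of the correction. No biological explanation was tested.

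Neighbouring genes changed together: windows of 30 genes with a median change of at least 0.5 (log2) numbered 92, 5, 2 and 17 in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2, 1 with trastuzumab and 7 with both antibodies, against at most 3 in 1000 random orders. After the GC correction they numbered 10, 2, 0 and 7 in the pools and 0 in both 3-day treatments, against at most 1 in random orders. With a cut of 0.3, chosen after seeing the data, 56, 34, 32 and 67 windows remained, against at most 16 in random orders and 4 in a 3-day treatment, which excludes GC content as the whole cause (at least 26 in any pool with 1 library left out or the median change set to 0). For a copy number difference from the parental line, more windows of 0.5 in every pool than in the 3-day treatments were predicted beforehand, which BT-TPR1 did not meet. Read by pool, a choice made after seeing the data, it fits in BT-TR1, BT-TR2 and BT-TPR2, though RNA alone does not show it. Nor can it be told in BT-TPR1, since 1 window reached 0.5 with the median change set to 0, and 13 of its 32 windows beyond 0.3 were falls on chromosome 14, as were 15 of 67 in BT-TPR2. The following corrected windows were singled out after their values were seen. On chromosome 14, from 73711783 to 76084585, the median was -0.49 in BT-TPR1 and -0.62 in BT-TPR2. On chromosome 1, from 629640 to 1600096, it was -0.78 in BT-TR1, -0.61 in BT-TR2, -0.42 in BT-TPR1 and -0.52 in BT-TPR2.

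With 3 libraries against 3, the 10 splits are too few for a share under 0.05, and 1, the real one, had as many genes in each comparison. The real counts were 1321, 2190, 153, 7693, 4387, 4815 and 5575 genes for trastuzumab, both antibodies, both antibodies against trastuzumab, BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2. The highest other split had 0 in edgeR each time, including the splits that part the replicate pairs as the real one does. At an unadjusted p under 0.05 the real splits had 3943, 4824, 913, 9126, 6632, 6902 and 7457 genes, and the highest other splits 2175, 2488, 2202, 4609, 2903, 2596 and 4214. For both antibodies against trastuzumab, splits with 2202, 1542 and 1044 genes exceeded the real 913, which points to structure beyond the groups. The shared deviation of replicate 1 libraries is a candidate. For the difference between the classes, the 4 pools can be split 3 ways, too few for a share under 0.05; the real split gave 424 genes and the others 34 and 15.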

How the results depend on the processing

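Replicates 2 and 3 alone, the GC correction (also with the block) and thinning were chosen only after the data were seen. DESeq2, RLE normalization, the strict filter and limma on the deposited transformed values left all 13 gene counts within 1.5 times. Leaving out 1 library gave 597 to 1412 for trastuzumab, 1104 to 2405 for both antibodies, 82 to 159 for both antibodies against trastuzumab, 5410 to 7983 for BT-TR1, 3028 to 4704 for BT-TR2, 3156 to 5088 for BT-TPR1, 3665 to 6451 for BT-TPR2, 2081 to 3250 for both BT-TR pools, 2549 to 3832 for both BT-TPR pools, 1313 to 2020 for all 4 pools, 304 to 426 for the class difference, 131 to 385 for trastuzumab shared with BT-TR and 354 to 803 for both antibodies shared with BT-TPR, and 86 to 94 list calls. A fold threshold of 2, which keeps fewer genes by construction, gave 277 for trastuzumab, 571 for both antibodies, 68 for both antibodies against trastuzumab, 2713 for BT-TR1, 1137 for BT-TR2, 1271 for BT-TPR1, 1646 for BT-TPR2, 808 for both BT-TR pools, 844 for both BT-TPR pools, 391 for all 4 pools, 139 for the class difference, 52 for trastuzumab shared with BT-TR and 105 for both antibodies shared with BT-TPR. With only the groups compared in the fit, fewer samples gave 381 for trastuzumab, 896 for both antibodies, 55 for both antibodies against trastuzumab, 2682 for BT-TR2, 3111 for BT-TPR1, 3060 for BT-TPR2, 204 for trastuzumab shared with BT-TR and 444 for both antibodies shared with BT-TPR. Without a filter there were 559 for trastuzumab shared with BT-TR, and with library size alone 206 for trastuzumab shared with BT-TR. The GC correction gave 2490 for trastuzumab, 3519 for both antibodies, 643 for the class difference, 794 for trastuzumab shared with BT-TR and 1204 for both antibodies shared with BT-TPR. The replicate block gave 4629 for trastuzumab, 5750 for both antibodies, 388 for both antibodies against trastuzumab, 8076 for BT-TR2, 8364 for BT-TPR1, 9019 for BT-TPR2, 5609 for both BT-TR pools, 6458 for both BT-TPR pools, 3807 for all 4 pools, 871 for the class difference, 1720 for trastuzumab shared with BT-TR and 2376 for both antibodies shared with BT-TPR. With both together there were 4846 for trastuzumab, 5917 for both antibodies, 452 for both antibodies against trastuzumab, 8318 for BT-TR2, 8582 for BT-TPR1, 9005 for BT-TPR2, 5678 for both BT-TR pools, 6492 for both BT-TPR pools, 3801 for all 4 pools, 1060 for the class difference, 1805 for trastuzumab shared with BT-TR and 2359 for both antibodies shared with BT-TPR. Replicates 2 and 3 alone gave 2472 for trastuzumab, 4008 for both antibodies, 696 for trastuzumab shared with BT-TR and 1609 for both antibodies shared with BT-TPR. Thinning gave 879 for trastuzumab and 92 for both antibodies against trastuzumab. With an estimated correlation, 17 of 91 list calls held. Of 258 called changes of named genes 226 kept their call and direction under all alternatives, as did 61 of 75 described list calls, the estimated correlation aside, while 9 of 16 list tests not called passed under at least 1 alternative. The CCND1 fall in BT-TPR2 reversed to 0.0585 with the GC correction and 0.0202 with the block added. Differences of the 10 genes reported in every group that passed no test turned sign in 17 of 40 cases, and 16 of the 40 passed under at least 1 alternative. With the GC correction they turned to 0.16 for ERBB2 in BT-TR1, 0.0833 for ERBB2 in BT-TR2, -0.00611 for PIK3CA between both antibodies and trastuzumab, 0.23 for CCND1 with trastuzumab and 0.0990 for CCND1 in BT-TR2. With the GC correction and replicate block they turned to 0.16 for ERBB2 in BT-TR1, 0.0821 for ERBB2 in BT-TR2, -0.00369 for ERBB3 in BT-TPR2, -0.00620 for PIK3CA between both antibodies and trastuzumab, 0.21 for CCND1 with trastuzumab and 0.0827 for CCND1 in BT-TR2. Scaled by library size alone they turned to 0.0121 for ERBB3 in BT-TPR1, 0.0290 for ERBB4 in BT-TPR2, 0.0299 for MKI67 in BT-TR2 and 0.0109 for MKI67 in BT-TPR1. With replicates 2 and 3 alone they turned to -0.0129 for ERBB3 in BT-TPR2 and 0.0838 for CCND1 with trastuzumab. For CCND1 in BT-TR1 they turned to -0.0164 without a filter, -0.0219 with only the groups compared and -0.00211 with the replicate block. Leaving out 1 library gave -0.28 to 0.00757 for ERBB2 between both antibodies and trastuzumab, -0.27 to 0.13 for ERBB2 in BT-TR2, -0.00653 to 0.12 for ERBB3 between both antibodies and trastuzumab, -0.0415 to 0.17 for ERBB3 in BT-TPR2, -0.12 to 0.0907 for ERBB4 in BT-TPR2, -0.0863 to 0.20 for PIK3CA between both antibodies and trastuzumab, -0.44 to 0.00904 for PPP1R1B with trastuzumab, -0.13 to 0.0252 for CCND1 with trastuzumab, -0.0334 to 0.13 for CCND1 with both antibodies, -0.0488 to 0.12 for CCND1 in BT-TR1, -0.32 to 0.0824 for MKI67 between both antibodies and trastuzumab, -0.22 to 0.0905 for MKI67 in BT-TR2, -0.28 to 0.0301 for MKI67 in BT-TPR1 and -0.26 to 0.0526 for MKI67 in BT-TPR2. For the other moves the cause was not tested. The median shift of all genes with the GC correction was -0.162 in BT-TR1 and 0.128 in BT-TPR1 against BT-TR1, and with library size alone 0.133 in the latter. Depth limits genes with few counts, such as OAS2 with 3 counts in BT-TPR2.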

Other observations

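The list tests were planned; these lists were picked after their values were seen. Of TGF beta and BMP targets, 9 and 9 of 24 fell in BT-TPR1 and BT-TPR2 (10 and 10 adjusted over the list alone). TGF beta and BMP targets had camera adjusted p of 0.018 and 0.0383, and adjusted p = 0.456 and 0.542 with an estimated correlation. In BT-TR1 and BT-TR2, 9 and 7 fell and camera did not call the list (0.497 and 0.146), nor did it between any BT-TPR and any BT-TR pool (0.246, 0.151, 0.335 and 0.309). It was called in BT-TPR1 against BT-TR1 with the GC correction (adjusted p = 0.0134) and with the block added (0.00847), range 0.00847 to 0.5, in BT-TPR1 against BT-TR2 without BT-TR2 replicate 2 (adjusted p = 0.0483), range 0.0483 to 0.473, and in BT-TR2 without a filter (adjusted p = 0.0441), range 0.0441 to 0.268. The largest changes were CTGF (-3.31 ± 0.57) and ID3 (-2.36 ± 0.25) in BT-TPR1 and ID1 (-2.88 ± 0.30) and ID3 (-2.73 ± 0.26) in BT-TPR2. CTGF held 4 counts in BT-TPR1 against 52 in untreated cells. The TGF beta and BMP targets call in BT-TPR2 ended without untreated replicate 1 (adjusted p = 0.0553), without BT-TPR2 replicate 2 or 3 (0.0844 and 0.0734), with the strict filter (0.0703), in limma (0.0632), with only the groups compared (0.0651), with the GC correction and replicate block (0.0911) or with thinning (0.0599), range 0.00951 to 0.0911.

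Of Hypoxia response genes, 11, 7, 6 and 9 of 19 rose in BT-TR1, BT-TR2, BT-TPR1 and BT-TPR2 (12, 9, 6 and 9 adjusted over the list alone). Hypoxia response had camera adjusted p of 0.000619, 0.0408, 0.039 and 0.00368, and adjusted p = 0.0626, 0.345, 0.303 and 0.181 with an estimated correlation. The largest changes by pool were LOX (2.20 ± 0.25) in BT-TR1, LOX (2.30 ± 0.24) in BT-TR2, MXI1 (1.79 ± 0.24) in BT-TPR1 and NDRG1 (1.77 ± 0.23) in BT-TPR2. The Hypoxia response call in BT-TR2 ended without untreated replicate 1 or 3 (adjusted p = 0.0921 and 0.0568), without BT-TR2 replicate 2 or 3 (0.0817 and 0.0717), with the strict filter (0.0557), scaled by library size alone (0.058), in limma (0.0663), with the replicate block (0.0817), with the GC correction (0.0815), with the GC correction and replicate block (0.0937) or with thinning (0.084), range 0.000639 to 0.0937. The Hypoxia response call in BT-TPR1 ended without untreated replicate 1 or 3 (adjusted p = 0.0854 and 0.0563), without BT-TPR1 replicate 3 (0.104), with the strict filter (0.0546), scaled by library size alone (0.0577), in limma (0.0619), with the GC correction (0.0842), with the GC correction and replicate block (0.0582) or with thinning (0.065), range 0.000516 to 0.104.

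Of the markers of other cell types, 4 of 18 fibroblast, 4 of 14 endothelial and 2 of 21 leukocyte genes passed the filter. Of the Fibroblast markers, 2, 1 and 2 of 4 fell in BT-TR1, BT-TR2 and BT-TPR2 (4, 2 and 2 adjusted over the list alone). Fibroblast markers had camera adjusted p of 0.00053, 0.000385 and 0.000436, and adjusted p = 0.0626, 0.128 and 0.181 with an estimated correlation, with the largest fall in CXCL14, also made by epithelial cells. The Fibroblast markers calls ended without a filter in BT-TR1 (adjusted p = 0.4), BT-TR2 (0.325) and BT-TPR2 (0.355). The ranges were 1.86e-06 to 0.4, 2.09e-05 to 0.325 and 7.22e-06 to 0.355. In none of 11 comparisons did camera call Basal markers, Lactation and secretion genes, Lysosome and autophagy or NF-kB and cytokine genes.

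Of 91 list calls over 7 comparisons, those not described elsewhere are listed by direction. With trastuzumab, higher levels were called for Apoptosis regulators and lower levels for Other receptor tyrosine kinases and ligands and Heat shock and dissociation stress. With both antibodies, higher levels were called for Apoptosis regulators and lower levels for Estrogen receptor targets, Fatty acid synthesis, MHC class I presentation, Endoplasmic reticulum chaperones, Notch pathway genes and Fibroblast markers. For both antibodies against trastuzumab, higher levels were called for FOXO and PI3K-repressed and ABC transporters and lower levels for ERBB receptors and ligands, Mitosis, Other receptor tyrosine kinases and ligands and Heat shock and dissociation stress. In BT-TR1, higher levels were called for 17q23 amplicon and Mitosis. In BT-TR2, higher levels were called for 17q12 HER2 amplicon and lower levels for ERBB receptors and ligands and Wnt pathway genes. In BT-TPR1, higher levels were called for Glycolysis and lower levels for ERK pathway output, Fatty acid synthesis and Mitochondrially encoded transcripts. In BT-TPR2, higher levels were called for 17q12 HER2 amplicon, Glycolysis and Heat shock and dissociation stress and lower levels for ERK pathway output and Wnt pathway genes. With an estimated correlation, of these only Apoptosis regulators with trastuzumab held (camera adjusted p of 0.0266, and adjusted p = 0.0479 with an estimated correlation). The Apoptosis regulators call with trastuzumab ended without untreated replicate 1 (adjusted p = 0.0636) or without trastuzumab replicate 3 (0.0698), range 0.000191 to 0.0698.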
